A study of Homo sapiens with 12 samples.

How the data were processed

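Messenger RNA was sequenced from 12 libraries of 2 human hepatocellular carcinoma cell lines, with 3 libraries in each of 4 groups. Huh7 cells carried a control mimic or a mimic of miR-628-3p, a synthetic double-stranded RNA that acts as the mature microRNA. MHCC97H cells carried an empty vector or a vector, named pGreen-628 in the labels, that expresses miR-628-3p. Per the labels, RNA was taken with Trizol, poly-A RNA was selected, the libraries kept the strand through dUTP, and fragments were read from both ends.

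The authors named HISAT2, HISAT and HTSeq with the builds GRCh38 and hg38, and gave no tool versions. Whether the counting used the strand is not given in the sources used here. The deposited table holds FPKM, fragments scaled to the exon length in kilobases and to the total of fragments counted over its genes, for 60664 genes by Ensembl identifier and with no further scaling between libraries. In every library each FPKM value times its exon length was a whole multiple of 1 step, so the read counts were worked back, with 100% of values within 0.01 reads of a whole number. The totals lay between 16472932 and 19578875 reads per library. Between 12456 and 12826 genes per library reached an FPKM of 1.

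Each line was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). Genes with a mean FPKM of at least 1 over the 6 libraries of the line entered the fit, with group as the term and eBayes with a mean-variance trend. A gene counts as called, as having risen or as having fallen where its Benjamini-Hochberg adjusted p over the genes tested in that line is under 0.05. Fold changes are miR-628-3p minus control on the log2 scale. Adding 1 pulls the fold of weakly expressed genes toward 0. The difference between the lines was an interaction term over all 12 libraries, coded as the effect in MHCC97H minus the effect in Huh7. The p values of single genes measure only the spread between these libraries, since nothing in the labels says that they came from separate cultures.

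A set of 38 gene lists was written before the data were examined, covering growth, stress, inflammation, metabolism, liver functions and signalling targets, with markers of fibroblasts, endothelial cells and leukocytes. A list needed 3 tested members in a comparison, and 37 lists had them in each comparison. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. At the preset correlation the p of camera rests mainly on the spread between genes, so small values do not measure the spread between libraries. Members were counted at the adjusted p over all genes and again adjusted over the list alone.

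Seed sites of miR-628-3p (UCUAGUAAGAGUGGCAGUCGA) were searched in the longest annotated 3′ UTR of 19090 genes of GENCODE release 29. A gene had a site where its UTR held TTACTAG, the match to the seed that includes the 8mer TTACTAGA. Genes with a site were compared with searched genes without one by camera. A regression on site presence, log UTR length and UTR GC content ranked TTACTAG among all sequences of 7 bases found in at least 100 genes. The searches and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

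Genes are named by a rule fixed before the data were examined. It takes MIR628 and its host CCPG1, the 10 largest rises and 10 largest falls per line among called protein-coding genes whose groups do not overlap, and up to 10 called genes that fell most among those with a seed site. It also takes up to 10 genes per direction called alike in both lines, up to 4 members with the smallest p of each list that passed or held 3 or more called members, and the 5 genes per direction with the smallest p for the difference between lines.

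The methods were tested on simulated counts of independent genes, with 1 dispersion per line (0.0035 in Huh7, 0.0014 in MHCC97H) estimated between its control libraries. Real libraries of a group could lie further apart. Between MHCC97H miR-628-3p libraries 2 and 3 the chi-square per degree of freedom across genes was 34.5, against 1.93 to 3.50 between vector libraries. The recovery rates that follow hold for the simulated spread only. With 3 libraries against 3, the test recovered 97.9% of planted changes of 2-fold and 74.2% of 1.5-fold in Huh7, and 93.8% and 85.9% in MHCC97H. A planted fall of 0.15 in genes with a seed site was measured as -0.13 in both lines. A planted trend with GC content gave 4426 false calls in Huh7 and 20 after the GC and length correction described next.

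Alternatives fixed beforehand changed the pseudocount, the expression filter, the scaling, the variance model, the joint fit of the lines, a block on replicate number, the gene types, the sites and the correlation for camera, and left out each library in turn. Alternatives added after seeing the data were limma voom on the recovered reads, and a correction of each library, blind to group, by splines of 5 degrees of freedom in transcript GC content and log exon length. Count-based tests from other packages were planned only for deposited counts and were not run, and the recovered reads were tested by voom alone.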

Results

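MiR-628-3p is a microRNA whose gene, MIR628, lies inside an intron of CCPG1, which encodes a receptor for selective autophagy of the endoplasmic reticulum. The study was designed to raise this microRNA in Huh7 and MHCC97H, lines grown from human hepatocellular carcinomas. It measured messenger RNA in 3 control and 3 miR-628-3p libraries of each. Delivery differed, by transfected mimic in Huh7 and by expression vector in MHCC97H. Reads per library averaged 17718700 ± 1354920 in the Huh7 control mimic, 17997300 ± 1381890 in the Huh7 miR-628-3p mimic, 17514000 ± 644707 in the MHCC97H vector and 18041600 ± 1364360 in the MHCC97H miR-628-3p vector. Here and below, ± after a level is the SD of 3 libraries.

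The annotated feature MIR628, 95 bases long (ENSG00000283891; GRCh38 chromosome 15, 55372940 to 55373034), had 0 reads in each of the 12 libraries, which allows up to 3 reads per library. Mature microRNAs carry no poly-A tail, so these libraries do not measure whether or how far miR-628-3p itself was raised. An effect of miR-628-3p below means the difference between the groups with and without its mimic or vector. CCPG1 (ENSG00000260916; chromosome 15, 55340032 to 55408510) was at 4.54 ± 1.16 FPKM in the Huh7 control and 6.33 ± 0.533 with the mimic (log2 fold change 0.42, adjusted p = 0.070). In MHCC97H it was at 16.6 ± 1.35 FPKM with the vector and 11.8 ± 3.18 with miR-628-3p (-0.48, adjusted p = 0.155). The 2 effects on CCPG1 differed from each other (adjusted p = 0.039), while neither was called within its line. The CCPG1 transcript has a GC content of 38.2%, against medians of 47.1% and 47.9% for genes tested in Huh7 and MHCC97H. Across genes, fold change correlated with GC content at a Spearman rho of -0.720 in Huh7 and 0.172 in MHCC97H. The difference on CCPG1 is therefore not separated from that trend.

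To ask what the mimic changed in Huh7, control and miR-628-3p libraries were compared gene by gene. The largest rises were in long transcripts, several of which encode proteins of cell division. CENPE, a kinetochore motor (ENSG00000138778; chromosome 4, 103105349 to 103198445), rose from 4.02 ± 1.34 to 17.4 ± 1.72 FPKM, a log2 fold change of 1.91 (SE 0.18, adjusted p = 0.027). KIF20B, a kinesin of cytokinesis, rose from 3.84 ± 1.48 to 10.2 ± 0.745 FPKM, and CENPF, another kinetochore protein, from 12.9 ± 5.63 to 27.0 ± 4.29. ASPM, a spindle pole protein, rose from 13.5 ± 6.19 to 27.7 ± 3.84 FPKM, and SGO2, which protects centromeric cohesin, from 15.0 ± 5.62 to 31.1 ± 1.87. The scaffold AKAP9, the golgin GOLGA4, the ciliary protein CEP290, the nucleolar protein ESF1 and the chromatin remodeller ATRX completed the 10 largest rises, with log2 fold changes between 1.04 and 1.37.

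The falls were smaller. BEST1, a chloride channel, fell from 39.1 ± 8.41 to 24.2 ± 1.16 FPKM (log2 fold change -0.65, adjusted p = 0.030). The mitochondrial ribosomal protein MRPL23 fell from 23.8 ± 1.40 to 15.4 ± 4.96 FPKM, and CHCHD10, a protein of mitochondrial cristae, from 23.4 ± 3.41 to 14.7 ± 1.54. The dynein light chain DYNLRB1, the lysosome positioning factors BLOC1S1 and BORCS8, and SAC3D1, FAM166A, GLTPD2 and PPDPF also fell, with log2 fold changes between -0.59 and -0.54.

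In all, 2642 of 12508 tested genes were called, 844 higher and 1798 lower, with 16 changed by at least 2-fold, 14 of them higher. The split by direction followed the scaling, with 1158 higher and 1121 lower after median rescaling and 1352 higher and 1394 lower after quantile normalization. The groups did not overlap for 6102 genes, 48.8% of those tested, where chance gives 10% on average over ways to split the libraries. Deviations from the gene mean correlated with GC content at a rho of 0.425 to 0.647 in control libraries and -0.650 to -0.461 in mimic libraries. Many of these genes thus moved together, and a single split can then lie far from that average. The smallest adjusted p was 0.027, and the count fell to 924, 1 and 1661 without control library 1, 2 or 3 and to 0, 4 and 0 without mimic library 1, 2 or 3.

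The Huh7 changes followed the base composition of the transcripts. Across genes, fold change correlated with transcript GC content at a Spearman rho of -0.720 and with exon length at 0.298, and both together held 48.1% of its variance. Genes called higher had a median GC content of 39.7%, against 57.7% for those called lower. The 10 named rises lay between 34.2% and 40.8%, and the 10 named falls between 49.5% and 73.5%. After the GC and length correction, 1 gene stayed called, CENPE at a log2 fold change of 1.63 (adjusted p = 0.0105), and 2889 of 12452 genes had an unadjusted p under 0.05, against 5236 of 12508 before. The other 9 named rises had log2 fold changes of 0.77 to 1.16, at adjusted p between 0.0877 and 0.131, among them AKAP9 at 1.11 (SE 0.17) against 1.37 (SE 0.24) before. Their standard errors did not grow, and fewer genes had small p values for the adjustment. The 10 named falls lay between -0.49 and -0.25. The median size of the fold change of the 2642 calls dropped from 0.29 to 0.12 on the log2 scale.

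**Figure D1:**
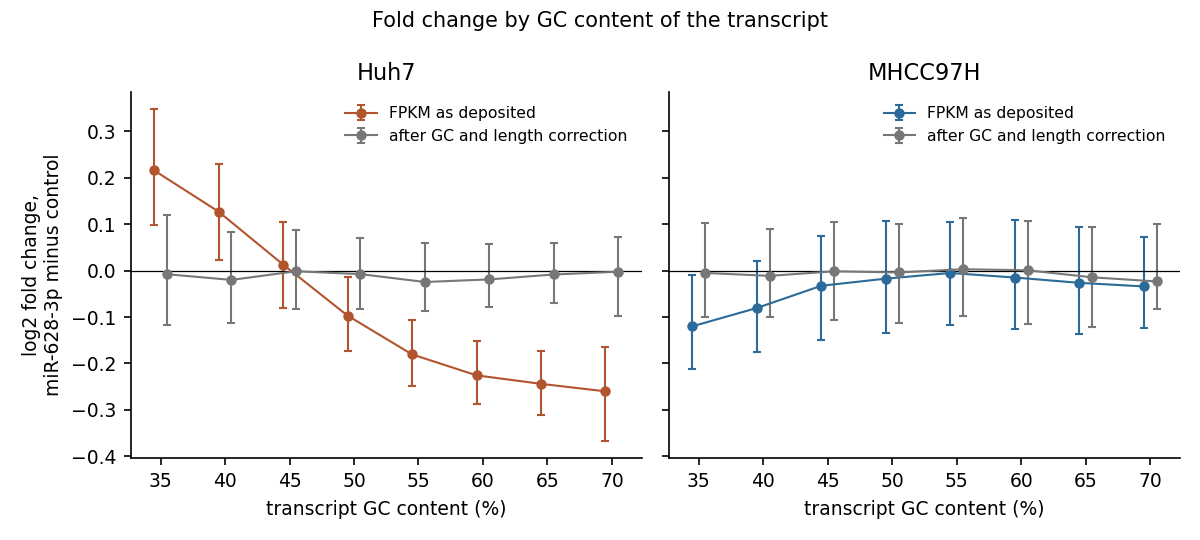
Median log2 fold change, miR-628-3p minus control, of tested genes in bins of transcript GC content (percent) in Huh7 and MHCC97H, with bars from the lower to the upper quartile of the genes. In Huh7 the FPKM as deposited run from higher to lower with GC content (rho -0.720), and the grey points after the GC and length correction lie near 0.

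Gene groups in Huh7 were next compared with all other genes. Of 44 ribosomal protein genes 10 fell and 0 rose, the same counts as when adjusted over the list alone, with a median log2 fold change of -0.19 (camera adjusted p = 0.000247, adjusted p = 0.83 with an estimated correlation). RPS2 fell from 1810 ± 106 to 1379 ± 81.4 FPKM and RPS15 from 1039 ± 75.1 to 799 ± 40.5. Of 33 nuclear genes of oxidative phosphorylation 12 fell and 0 rose, or 16 and 0 adjusted over the list alone (adjusted p = 0.00028, adjusted p = 0.83 with an estimated correlation). UQCRC1 of complex III fell from 140 ± 4.04 to 111 ± 0.961 FPKM, CYC1 of the same complex from 104 ± 6.46 to 84.8 ± 2.67, and NDUFS7 of complex I from 40.0 ± 3.12 to 31.0 ± 1.83. Of 19 glycolysis genes 8 fell and 0 rose, or 9 and 0 adjusted over the list alone (adjusted p = 0.0156, adjusted p = 0.83 with an estimated correlation). Pyruvate kinase PKM fell from 931 ± 43.8 to 762 ± 34.5 FPKM, PFKL from 22.5 ± 1.71 to 17.7 ± 0.281 and the lactate exporter SLC16A3 from 34.4 ± 2.30 to 27.6 ± 0.228.

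The mitosis list split. Of its 28 members 9 rose and 6 fell, or 13 and 6 adjusted over the list alone, with a median log2 fold change of 0.15 (adjusted p = 0.0334, adjusted p = 0.83 with an estimated correlation). Besides CENPE, topoisomerase TOP2A rose from 69.1 ± 14.8 to 101 ± 2.92 FPKM, while the kinase AURKB fell from 48.6 ± 3.78 to 39.7 ± 1.90 and UBE2C, an enzyme that marks mitotic proteins for degradation, from 55.8 ± 1.16 to 49.1 ± 0.812. These were 4 of the 37 lists to pass. After the GC and length correction mitosis, oxidative phosphorylation and ribosomal proteins still passed at the preset correlation (adjusted p = 0.85 for each with an estimated correlation) and glycolysis did not (adjusted p = 0.27, median -0.06 against -0.17 before). The YAP and TEAD targets passed upward after the correction and not before it (adjusted p = 0.0212 and 0.178, and 0.85 after it with an estimated correlation). The medians of the 3 lists that still passed were then 0.12, -0.09 and -0.10, against 0.15, -0.19 and -0.19 before, and 1 mitosis gene, CENPE, and 0 members of the other lists were called. Quantile normalization ended the calls of ribosomal proteins (adjusted p = 0.328, median -0.029 against -0.19) and glycolysis (adjusted p = 0.117, median -0.13 against -0.17). A joint fit of the lines ended the glycolysis call (adjusted p = 0.106), and leaving out mimic library 2 that of mitosis (adjusted p = 0.0740).

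Other groups held called genes without passing as lists in Huh7. Of 25 cholesterol synthesis genes 10 fell and 2 rose, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.135). The falls took in the sterol regulator SREBF2, from 25.0 ± 1.05 to 20.1 ± 0.797 FPKM, and mevalonate kinase MVK, from 23.6 ± 1.12 to 19.1 ± 1.09. Of 26 antioxidant and ferroptosis genes 10 fell and 3 rose, or 11 and 4 adjusted over the list alone (adjusted p = 0.373), among them the heme oxygenase HMOX1, from 20.3 ± 0.943 to 15.8 ± 1.07 FPKM. Of 27 hepatocyte genes 8 fell and 3 rose, or 9 and 4 adjusted over the list alone (adjusted p = 0.607). The liver transcription factor CEBPA fell from 90.4 ± 3.88 to 74.2 ± 2.11 FPKM and the apolipoprotein APOA1 from 102 ± 5.15 to 79.6 ± 7.44. Of 24 hypoxia genes 4 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.563), with HIF1A, the oxygen-regulated transcription factor, rising from 125 ± 21.5 to 173 ± 8.12 FPKM. None of the genes named in this paragraph was called after the GC and length correction.

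To ask the same of MHCC97H, the vector and miR-628-3p vector libraries were compared. CDKN1C, an inhibitor of cyclin-dependent kinases (ENSG00000129757; chromosome 11, 2883213 to 2885775), rose from 5.42 ± 0.407 to 21.8 ± 3.04 FPKM, a log2 fold change of 1.82 (SE 0.11, adjusted p = 0.000443). CDH1, which encodes the epithelial adhesion protein E-cadherin (ENSG00000039068; chromosome 16, 68737292 to 68835537), rose from 3.22 ± 0.0731 to 9.45 ± 0.183 FPKM (1.31, adjusted p = 0.000185). Albumin (ALB), the main secreted protein of hepatocytes, rose from 13.9 ± 0.571 to 39.8 ± 2.66 FPKM, and NDRG1, a stress and hypoxia response gene, from 121 ± 10.1 to 330 ± 51.5. The replication-dependent histone gene H4C8 rose from 27.4 ± 3.80 to 108 ± 24.7 FPKM and the growth factor binding protein IGFBP5 from 7.35 ± 0.411 to 23.2 ± 3.92. The glucose transporter SLC2A3, the adhesion molecule CEACAM5, the collagen COL5A2 and the lipase LIPE completed the 10 largest rises, with log2 fold changes between 1.22 and 1.56.

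PLAT, the tissue plasminogen activator (ENSG00000104368; chromosome 8, 42174718 to 42207709), fell from 33.1 ± 1.13 to 7.01 ± 0.562 FPKM, a log2 fold change of -2.09 (SE 0.073, adjusted p = 6.99e-05). The cystatins CST1, CST2 and CST4, inhibitors of cysteine proteases encoded close together on chromosome 20, fell from 30.3 ± 1.93 to 5.87 ± 0.959, from 4.34 ± 0.366 to 0.496 ± 0.0838 and from 4.59 ± 0.551 to 0.305 ± 0.173 FPKM. These paralogs are alike in sequence, and how reads that match several of them were counted is not given in the sources used here. The chemokine CCL20 fell from 26.9 ± 0.370 to 10.1 ± 0.0693 FPKM, and CHAC1, a glutathione-degrading enzyme, from 6.09 ± 0.668 to 1.95 ± 0.150. CD79A, known from the B cell receptor, the cytokine signalling inhibitor SOCS2, the annexin ANXA3 and ANKRD29 completed the 10 largest falls, with log2 fold changes between -1.52 and -1.13.

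**Figure D2:**
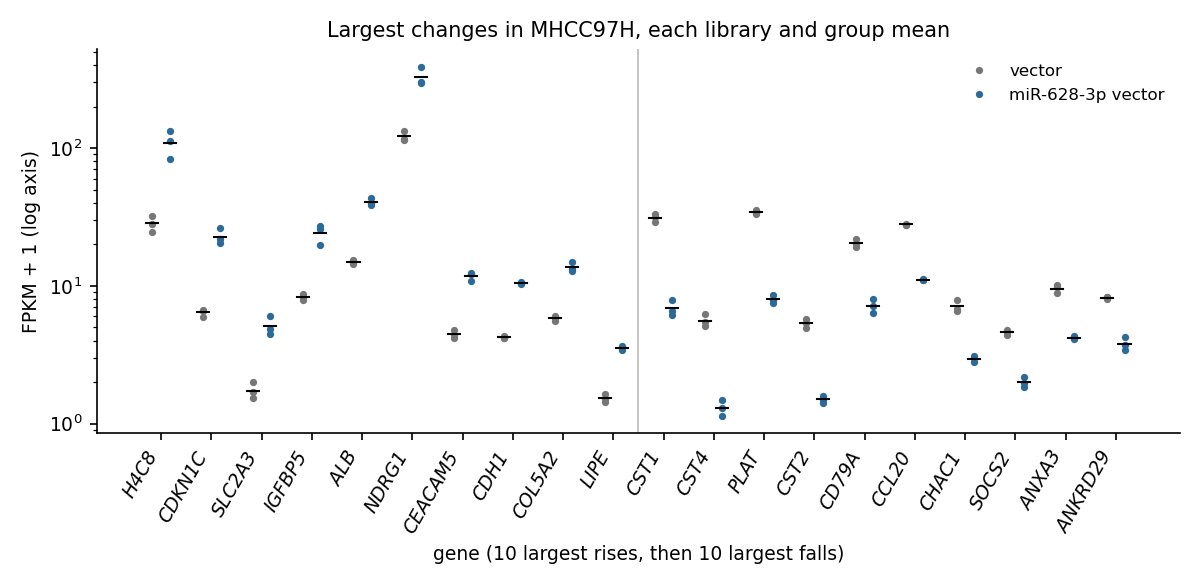
FPKM plus 1 on a log axis for the 10 largest rises and 10 largest falls in MHCC97H. Each point is 1 of 3 libraries per group, grey for the vector and blue for the miR-628-3p vector, and each bar is the mean. The groups do not overlap for any of these genes, which were chosen for that, as for PLAT at 33.1 ± 1.13 and 7.01 ± 0.562.

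In all, 680 of 12670 tested genes were called in MHCC97H, 294 higher and 386 lower, with 41 changed by at least 2-fold, 21 of them higher. After median rescaling 388 were higher and 329 lower, and after quantile normalization 417 and 324. The groups did not overlap for 3795 genes, 30.0% of those tested, where chance gives 10% on average over ways to split the libraries. Each of the 20 genes with the largest rises and falls was called in each of the 19 other settings in which it passed the expression filter. The count was 145, 185 and 142 without vector library 1, 2 or 3, 166 without miR-628-3p library 1 and 1604 without miR-628-3p library 3. GC content and length together held 7.38% of the variance of these fold changes, and after the correction for both 1981 genes were called, 645 of the 680 among them with the same sign.

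In MHCC97H, of 25 targets of ATF4, the transcription factor of the integrated stress response, 13 fell and 0 rose, or 19 and 0 adjusted over the list alone, with a median log2 fold change of -0.43 (camera adjusted p = 1.04e-12, adjusted p = 0.064 with an estimated correlation and 0.0241 with it after the GC and length correction). Besides CHAC1, the cystathionase CTH fell from 10.9 ± 0.264 to 5.77 ± 0.873 FPKM, ATF3 from 18.2 ± 1.34 to 11.8 ± 0.206 and the serine synthesis enzyme PSAT1 from 154 ± 6.26 to 107 ± 5.19. Of 21 inflammatory NF-kB targets 10 fell and 0 rose, or 15 and 1 adjusted over the list alone, with a median of -0.42 (adjusted p = 1.38e-08, adjusted p = 0.064 with an estimated correlation). Along with CCL20, the chemokines CXCL5, CXCL2 and CXCL8 fell, CXCL5 from 86.2 ± 1.55 to 53.9 ± 3.47 FPKM and CXCL8 from 6.42 ± 0.468 to 3.02 ± 0.302.

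Of 24 cholesterol synthesis genes 8 fell and 0 rose, or 19 and 0 adjusted over the list alone, with a median of -0.32 (adjusted p = 1.39e-08, adjusted p = 0.064 with an estimated correlation). ACAT2, which makes acetoacetyl-CoA, fell from 41.9 ± 0.220 to 26.6 ± 1.82 FPKM, the sterol oxidase MSMO1 from 44.9 ± 1.65 to 29.1 ± 1.77 and squalene epoxidase SQLE from 44.7 ± 0.654 to 33.7 ± 1.59. Of 24 immediate early targets of MAPK signalling 10 fell and 0 rose, or 14 and 0 adjusted over the list alone, with a median of -0.33 (adjusted p = 9.22e-06, adjusted p = 0.163 with an estimated correlation). The phosphatases DUSP4 and DUSP1 fell from 59.4 ± 1.26 to 39.1 ± 0.892 and from 14.1 ± 1.42 to 6.52 ± 0.861 FPKM, and PHLDA1 from 108 ± 1.73 to 81.0 ± 2.57. Of 4 acute phase genes the fibrinogen chains FGB and FGG fell, 3 members adjusted over the list alone and 0 rose (adjusted p = 0.00794, adjusted p = 0.143 with an estimated correlation). FGB went from 3.86 ± 0.278 to 2.12 ± 0.0678 FPKM and FGG from 3.33 ± 0.504 to 1.66 ± 0.301. The acute phase call was lost without the expression filter (adjusted p = 0.183) and in a joint fit of the lines (adjusted p = 0.361).

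Of 24 hypoxia targets 10 rose and 0 fell, or 15 and 3 adjusted over the list alone, with a median of 0.32 (adjusted p = 2.65e-10, adjusted p = 0.087 with an estimated correlation). Besides NDRG1, carbonic anhydrase CA9 rose from 15.1 ± 0.642 to 36.2 ± 6.39 FPKM, the lipid droplet protein HILPDA from 15.7 ± 0.703 to 27.0 ± 2.87 and the lipase inhibitor ANGPTL4 from 15.7 ± 1.71 to 35.1 ± 7.04. Of 21 glycolysis genes 2 rose and 0 fell, or 4 and 0 adjusted over the list alone (adjusted p = 3.16e-05, adjusted p = 0.378 with an estimated correlation). They were SLC2A3, from 0.736 ± 0.232 to 4.11 ± 0.829 FPKM, and PFKFB3, a regulator of glycolytic flux, from 32.4 ± 2.15 to 41.7 ± 2.62. Of 20 fatty acid oxidation genes 2 rose and 0 fell, or 7 and 0 adjusted over the list alone (adjusted p = 1.19e-05, adjusted p = 0.064 with an estimated correlation). PDK4, which inhibits pyruvate dehydrogenase, rose from 5.56 ± 0.0857 to 8.28 ± 0.819 FPKM.

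The epithelial and mesenchymal lists both passed upward. Of 17 epithelial genes 3 rose and 0 fell, or 6 and 0 adjusted over the list alone, with a median of 0.23 (adjusted p = 4.71e-06, adjusted p = 0.143 with an estimated correlation). With CDH1, the tight junction gene CLDN7 rose from 11.8 ± 0.628 to 22.6 ± 2.36 FPKM and the mucin MUC1 from 2.17 ± 0.218 to 4.28 ± 0.660. Of 16 mesenchymal genes 4 rose and 0 fell, or 6 and 2 adjusted over the list alone, with a median of 0.16 (adjusted p = 0.00346, adjusted p = 0.126 with an estimated correlation). The collagen crosslinking enzyme LOX rose from 2.23 ± 0.457 to 5.00 ± 0.504 FPKM, the protease MMP14 from 13.3 ± 0.356 to 18.7 ± 1.75 and fibronectin FN1 from 1763 ± 75.1 to 2249 ± 158. The mesenchymal list did not pass at a mean FPKM of at least 5 (adjusted p = 0.115). Of 4 fibroblast markers 0 were called, or 1 rose adjusted over the list alone (adjusted p = 0.0430, adjusted p = 0.214 with an estimated correlation). Their most abundant member FBLN1 was at 29.7 ± 1.47 and 33.4 ± 2.27 FPKM, and LUM at 1.82 ± 0.213 and 2.68 ± 0.343. That call was lost after median rescaling (adjusted p = 0.0596), without the expression filter (adjusted p = 0.130), in the joint fit (adjusted p = 0.0615) and without vector library 3 (adjusted p = 0.0860). The 3 endothelial markers tested did not pass as a list (adjusted p = 0.225, 1 rose and 0 fell, also adjusted over the list alone), and neither did the 3 leukocyte markers tested in Huh7 (adjusted p = 0.607, 0 called).

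Of 23 genes of the unfolded protein response 6 rose and 0 fell, or 8 and 0 adjusted over the list alone, with a median of 0.11 (adjusted p = 3.53e-05, adjusted p = 0.064 with an estimated correlation). The protein disulfide isomerases PDIA4 and PDIA3 rose from 96.1 ± 2.46 to 122 ± 2.78 and from 120 ± 3.64 to 150 ± 2.44 FPKM, and the chaperone CALR from 279 ± 5.60 to 357 ± 25.5. Of 12 progenitor and oncofetal genes 3 rose and 1 fell, or 6 and 2 adjusted over the list alone (adjusted p = 0.00825, adjusted p = 0.143 with an estimated correlation). The imprinted noncoding RNA H19 rose from 37.7 ± 14.6 to 131 ± 47.1 FPKM and CD24 from 199 ± 6.68 to 253 ± 4.76, while the transcription factor SOX4 fell from 51.4 ± 0.899 to 41.5 ± 1.92. Of 8 histone genes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (adjusted p = 0.0450, adjusted p = 0.378 with an estimated correlation). With H4C8, H2BC5 and H1-2 rose and H2BC21 fell from 4.26 ± 0.321 to 2.81 ± 0.253 FPKM. Most histone messages carry no poly-A tail, so these libraries hold only a part of them. The histone call was lost in 9 of the 19 other settings, at adjusted p between 0.0527 with voom and 0.177 without the expression filter, and among them without miR-628-3p library 2 (adjusted p = 0.154) or vector library 2 (adjusted p = 0.0571).

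Among the remaining lists that passed, 1 of 11 WNT targets rose, or 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.00692, adjusted p = 0.163 with an estimated correlation). It was TBX3, a transcription factor, from 2.03 ± 0.151 to 3.05 ± 0.273 FPKM. Of 28 mitosis genes 1 rose, or 0 adjusted over the list alone (adjusted p = 0.00794, adjusted p = 0.227 with an estimated correlation), the kinesin KIF20A, from 16.5 ± 1.44 to 21.4 ± 1.34 FPKM. Of 10 transporters of bile acids and drugs 1 rose, or 3 adjusted over the list alone (adjusted p = 0.0351, adjusted p = 0.349 with an estimated correlation), the exporter ABCG2, from 51.1 ± 0.605 to 67.3 ± 4.93 FPKM. The transporter call was lost after the GC and length correction (adjusted p = 0.121), with a median of 0.09 before and after it, at a mean FPKM of at least 5 (adjusted p = 0.0523) and without miR-628-3p library 3 (adjusted p = 0.278) or vector library 2 or 3 (adjusted p = 0.0589 and 0.0550). In all 17 of 37 lists passed, 12 up and 5 down. With an estimated correlation 0 passed after adjustment and 10 had an unadjusted p under 0.05, and fry called 19. After the GC and length correction p53 targets and MYC targets of ribosome biogenesis also passed downward (adjusted p = 0.0194 and 0.0239, against 0.0723 and 0.0781 before). With an estimated correlation they did not pass after it (adjusted p = 0.180 and 0.199). The histone call was lost after the correction (0.0722) at a median of 0.31, against 0.23 before.

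**Figure D3:**
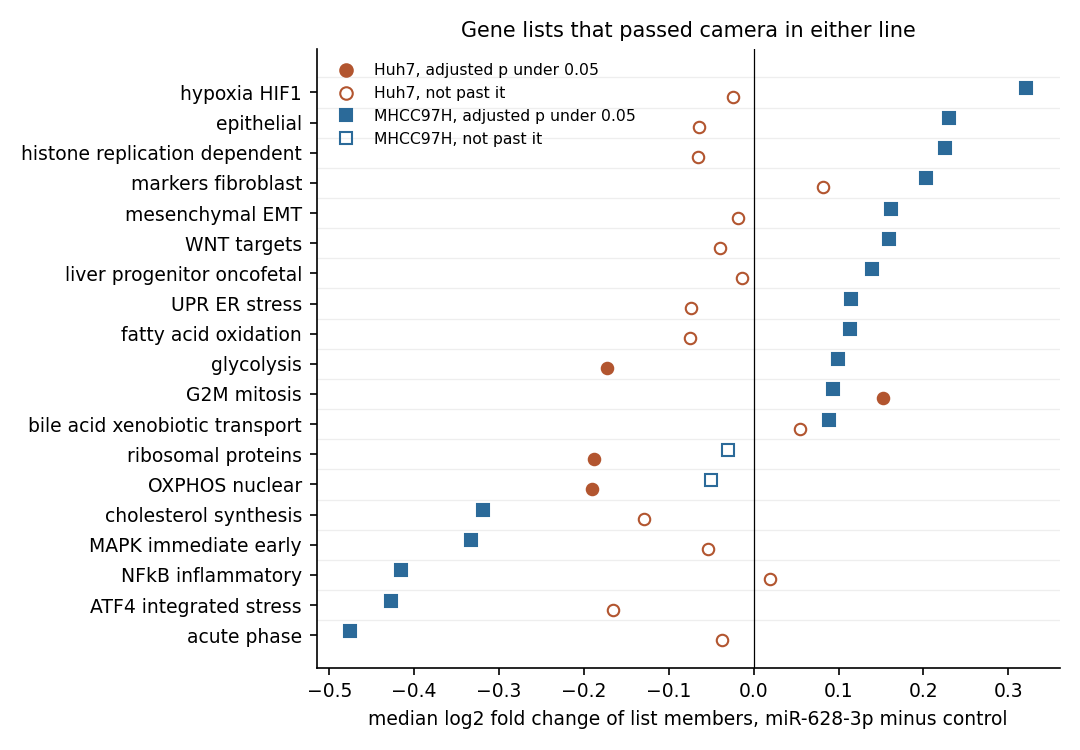
Median log2 fold change, miR-628-3p minus control, of the tested members of each gene list that passed camera in either line, with circles for Huh7 and squares for MHCC97H. Filled symbols mark lists past the threshold at the preset correlation, 4 in Huh7 and 17 in MHCC97H. The ATF4 list has its median at -0.43 and the hypoxia list at 0.32 in MHCC97H.

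Whether the effect itself differed between the lines was tested next. It differed for 1694 of 13171 genes, 979 with the higher value in MHCC97H. CDKN1C was at 0.490 ± 0.0513 FPKM in the Huh7 control and 0.333 ± 0.0413 with the mimic, and its difference in effect was 1.98 on the log2 scale (SE 0.13, adjusted p = 8.07e-06). CDH1 was at 21.5 ± 0.233 and 20.6 ± 1.97 FPKM in Huh7 (difference 1.37), albumin ALB at 6616 ± 246 and 7268 ± 544 (1.32) and COL5A2 at 41.7 ± 0.529 and 45.2 ± 2.46 (1.11). CCL20 was at 715 ± 4.60 and 747 ± 63.1 FPKM in Huh7 (difference -1.39) and PLAT at 0.811 ± 0.221 and 0.808 ± 0.0639 (-2.10). In Huh7 CDKN1C and PLAT lay under the mean FPKM of 1 needed for the fit of that line. Adding 1 pulls their Huh7 effects toward 0, so their differences rest mainly on MHCC97H. CEACAM5, CST1, CST2 and CST4 were listed at 0 in all 6 Huh7 libraries, so their differences, of 1.40, -2.19, -1.83 and -2.10, restate the change in MHCC97H. The CEACAM5 difference was not past the threshold with voom (adjusted p = 0.0843).

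As groups, hypoxia, glycolysis, WNT, fatty acid oxidation, epithelial, ribosomal protein and unfolded protein response genes had higher effects in MHCC97H than in Huh7, and NF-kB, ATF4, MAPK and cholesterol genes lower ones. These 11 lists passed camera for the difference, with adjusted p between 1.61e-05 and 0.0122, and 0 passed with an estimated correlation, at adjusted p between 0.089 and 0.79. After the GC and length correction the ATF4, MAPK and unfolded protein response lists passed with an estimated correlation (adjusted p = 0.0108, 0.0309 and 0.0337). Oxidative phosphorylation and the YAP and TEAD targets then passed at the preset correlation (adjusted p = 0.0432 and 0.00504, against 0.125 and 0.0789 before). With an estimated correlation these 2 did not pass (adjusted p = 0.63 and 0.268). The ribosomal protein call was lost under quantile normalization (adjusted p = 0.268) and without Huh7 mimic library 3 (0.138) or MHCC97H miR-628-3p library 2 (0.0835), the WNT call after the GC and length correction (0.0775, median 0.16 against 0.30 before) and at a mean FPKM of at least 5 (0.398), and the MAPK call without MHCC97H miR-628-3p library 3 (0.0528). Of the 25 hypoxia genes 12 had a higher effect in MHCC97H and 1 a lower one, or 13 and 2 adjusted over the list alone. Of the 22 NF-kB genes 11 had a lower effect and 0 a higher one, or 11 and 2 adjusted over the list alone. The count of genes was 4670 without MHCC97H miR-628-3p library 3 and 637 without MHCC97H vector library 3. It was 705, 1044, 845 and 1040 without Huh7 control library 1 or 2 or mimic library 1 or 2, and 831, 1099 and 650 without MHCC97H miR-628-3p library 1 or 2 or vector library 1.

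Few genes were called alike in both lines. The 7 genes higher in both, against 13.7 expected from the numbers of calls (Fisher's exact test across 10910 genes, two-sided p = 0.064), included CDH17, a liver-intestine cadherin, and GJA1, the gap junction protein connexin 43. CDH17 went from 5.29 ± 0.164 to 6.76 ± 0.167 FPKM in Huh7 and from 79.1 ± 0.601 to 119 ± 11.7 in MHCC97H. The 23 genes lower in both, against 44.5 expected (Fisher's exact p = 0.000178), included SPHK1, which makes sphingosine-1-phosphate, HMOX1, MVK and the sterol isomerase EBP. SPHK1 went from 6.08 ± 0.563 to 4.22 ± 0.249 FPKM in Huh7 and from 15.4 ± 0.416 to 10.0 ± 0.950 in MHCC97H. Another 33 genes were called in opposite directions, against 50.7 expected. Genes are not independent replicates, so these p values describe the overlap only. Across genes the fold changes of the lines correlated at a Pearson r of -0.108 and a Spearman rho of -0.117, and r was 0.187 without MHCC97H miR-628-3p library 2. The count of 30 shared genes was 56 without that library, 47 without MHCC97H miR-628-3p library 3, 8 without miR-628-3p library 1, and 6, 8 and 5 without vector library 1, 2 or 3. It was 11 and 0 without Huh7 control library 1 or 2, and 0 without any 1 of the mimic libraries. After the GC and length correction 0 genes were called alike and 0 in opposite directions. Fold change ran with GC content in opposite directions in the lines (rho -0.720 in Huh7 and 0.172 in MHCC97H). The overlap counts and the named shared genes are therefore not separated from that trend.

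A microRNA pairs with sites in the 3′ UTR through its seed, and the last comparison asked whether genes with a miR-628-3p seed site fell. In Huh7, 867 genes with a site had a mean log2 fold change 0.13 above that of 9593 searched genes without one (camera p = 1.08e-09, p = 0.095 with an estimated correlation). Among genes called lower 2.05% held a site, against 8.29% of all searched genes. In a regression that took in UTR length, UTR GC content, transcript GC content and exon length, a site carried 0.0005 on the log2 scale (95% interval -0.0093 to 0.0104). This interval, like those of sites below, takes genes as independent. After the GC and length correction the shift was -0.017 (camera p = 0.27, p = 0.56 with an estimated correlation). OAF, SLC35A2, MOB3A and VAT1 were among the called genes with a site that fell most, SLC35A2, a transporter of UDP-galactose, from 90.1 ± 3.09 to 70.3 ± 4.15 FPKM.

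In MHCC97H, 844 genes with a site differed from 9940 without one by -0.0060 on the log2 scale (p = 0.77, p = 0.96 with an estimated correlation). The shift was -0.072 without miR-628-3p library 3 and 0.054 without miR-628-3p library 2, each past the threshold at the preset correlation (camera p = 0.0011 and p = 0.016). Among genes called lower 3.94% held a site, against 7.83% of all searched genes (odds ratio 0.475, 95% interval 0.249 to 0.829, and 0.825, 0.613 to 1.09, after the GC and length correction). Called genes with a site that fell most included PMAIP1, which encodes the apoptosis factor NOXA, from 32.1 ± 1.38 to 18.0 ± 2.35 FPKM, METAP2, which removes the first methionine of proteins, from 55.6 ± 1.80 to 34.4 ± 4.05, the sterol gene IDI1 from 52.1 ± 1.75 to 34.1 ± 4.23 and the cholesterol carrier NPC1 from 64.1 ± 3.26 to 45.7 ± 2.30. Counted from the lowest regression coefficient, the seed match TTACTAG ranked 14513 of 15649 sequences of 7 bases in Huh7 and 1766 of 15697 in MHCC97H, and 8805 and 5626 after the GC and length correction.

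**Figure D4:**
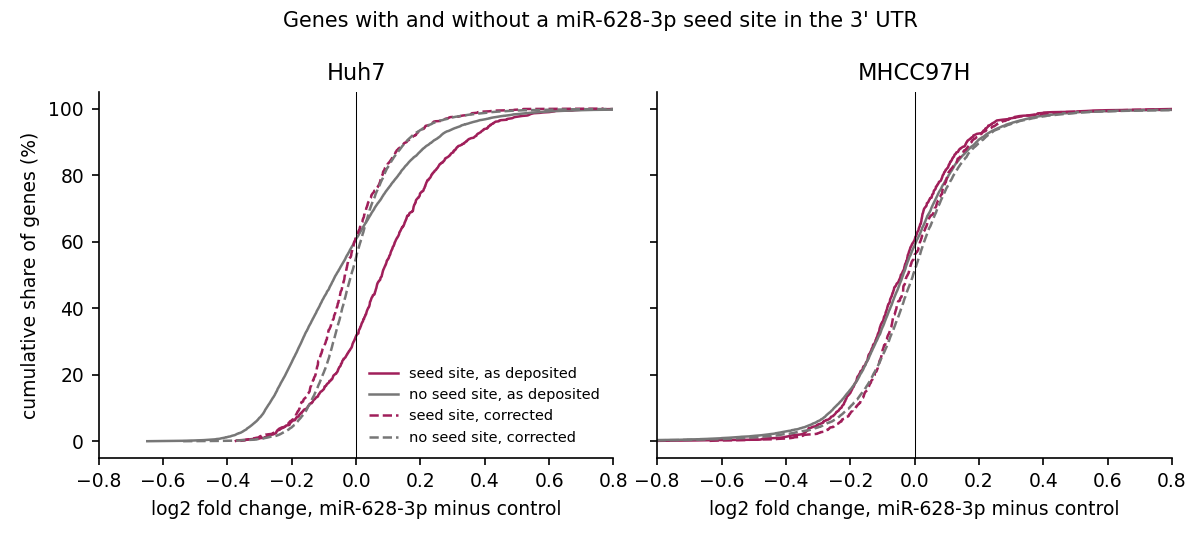
Cumulative share of genes (percent) by log2 fold change, miR-628-3p minus control, for genes with a miR-628-3p seed site (magenta) and searched genes without one (grey), as deposited (solid) and after the GC and length correction (dashed). The solid magenta line of Huh7 lies to the right of the grey one, by 0.13 on average, and the lines of MHCC97H lie close together.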

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

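The tests on the Huh7 changes and on the MHCC97H gene groups below were chosen after their results were seen, and those on sharing between the lines and on regrouped libraries were not. The tests on sharing do use the GC and length correction, itself added after seeing the data. The effect of miR-628-3p differed between the lines for 1694 genes, by an interaction term over all 12 libraries. Of 253 named genes with a tested difference, 123 differed, 67 with the higher effect in MHCC97H, against 1694 of all 13171 genes tested. The named genes were picked from these data, some by the p of this same difference, so a larger share follows from the choice. On the log2 scale, MHCC97H minus Huh7, the differences with the smallest p were 1.98 for CDKN1C, 1.37 for CDH1, 1.32 for ALB, 1.40 for CEACAM5 and 1.11 for COL5A2, and -1.83 for CST2, -2.19 for CST1, -1.39 for CCL20, -2.10 for PLAT and -2.10 for CST4. The lists that differed had median differences of 0.21 for epithelial genes, -0.30 for NF-kB, 0.14 for the unfolded protein response, -0.23 for ATF4, -0.17 for cholesterol synthesis, 0.24 for fatty acid oxidation, 0.30 for glycolysis, 0.30 for hypoxia, 0.16 for ribosomal proteins, 0.30 for WNT and -0.20 for MAPK targets. They passed at the preset correlation, and 0 passed with an estimated correlation (adjusted p between 0.089 and 0.79), while after the GC and length correction 3 did, ATF4, MAPK and the unfolded protein response (adjusted p = 0.0108, 0.0309 and 0.0337). The WNT, ribosomal protein and MAPK calls were also lost under other settings, given above.

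In Huh7, fold changes ran with the GC content of transcripts, and some libraries of 1 and the same group differed along the same genes. Over the 12 pairs of libraries that share a group, the size of the correlation between the Huh7 fold changes and the difference of the pair ran from 0.0570, for Huh7 control libraries 2 and 3, to 0.757. The strongest, r = -0.757 across 10910 genes, was for miR-628-3p libraries 2 and 3 of MHCC97H, so a technical trend in library preparation is a candidate explanation for much of the Huh7 response. Repression through seed sites is argued against as the main source of these changes, since 2.05% of genes called lower in Huh7 held a site. The adjusted coefficient of a site had a 95% interval whose lower end was -0.0093 on the log2 scale, and -0.0185 after the GC and length correction. These intervals take genes as independent and are likely too narrow. The estimated correlation between site genes was 0.087 in Huh7, and 0.033 after the correction. A small fall of site genes stays open: after the correction they lay 0.017 lower in Huh7 and 0.0057 lower in MHCC97H, each at an exact p of 0.1, the smallest that 10 splits can give. Genes with a site of miR-628-5p (GTCAGCA) lay 0.029 lower in Huh7 after the correction and 0.0046 higher in MHCC97H. A fall of this size in Huh7 was thus not particular to sites of miR-628-3p. An effect of the mimic on long AT-rich transcripts may still be part of it, because the groups and the trend go together in these 6 libraries and a correction removes both alike. CENPE stayed called after the correction, and the other 9 largest rises lost their calls (adjusted p between 0.0877 and 0.131) at log2 fold changes of 0.77 to 1.16, against 1.04 to 1.37 before, which leaves open how far the trend accounts for them.

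In MHCC97H, 13 of 25 ATF4 targets, 10 of 21 NF-kB targets and 8 of 24 cholesterol genes fell, and 10 of 24 hypoxia and 6 of 23 unfolded protein response genes rose. These lists passed at the preset correlation, and not with an estimated correlation (adjusted p between 0.064 and 0.087). After the GC and length correction the ATF4 list passed with an estimated correlation (adjusted p = 0.0241) and the other 4 did not (0.0984 to 0.18). The GC and length trend is argued against as the whole cause, since 15 of the 17 lists still passed in the same direction after the correction. A single deviating library is argued against only for the list calls at the preset correlation, since each fit without 1 library left at least 15 of the 17 passing. That setting is lenient, as other splits of these libraries passed 4 to 13 lists while calling 0 genes. The gene calls did lean on single libraries, with 142 to 1604 called without 1 library. The called falls had odds of holding a seed site with a 95% interval whose upper end was 0.829, and 1.09 after the correction. These odds were not adjusted for length, and called falls had a median exon length of 1969 bases, against 3584.5 for called rises. Shorter transcripts may hold fewer sites, so the odds cannot decide on direct repression. The coefficient of a site adjusted for length and GC content was -0.012 (95% interval -0.0265 to 0.0025). That interval takes genes as independent, while the estimated correlation between site genes was 0.327, so it is likely too narrow. A response to miR-628-3p that passes through other regulators may remain, as may a difference in cell density, medium or selection between the vector cultures, neither of which was tested.

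Few calls were shared between the lines, with 30 genes called in the same direction (0 after the GC and length correction), and the correlation of fold changes was unstable. GC and length bias may account for that instability: over the 12 fits without 1 library r spanned 0.601, from -0.413 to 0.187, and after the correction it spanned 0.257, from -0.194 to 0.0636. That the MHCC97H response was present in Huh7 but too small to call is argued against. Of 645 genes called in MHCC97H with and without the correction, 450 were also tested in Huh7. Over these the slope of the corrected Huh7 on the corrected MHCC97H fold change was -0.0328, between -0.0342 and -0.0229 without 1 Huh7 library, and 48% of the genes had the same sign. The correction would also remove a shared response that ran with GC content or length, so the slope covers only a response apart from that trend. The lines also differ in origin and in delivery, by mimic or vector, and the design does not separate these.

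Regrouping the 6 libraries of a line gives 10 splits, too few for a share under 0.05. In Huh7 the real split called 2642 genes, 16 of them by 2-fold, and the highest other split 0 and 0 (1 of 10 splits as large in each). The seed shift was 0.13 in size against 0.079 (1 of 10), and 4 lists passed against 9 (4 of 10). In MHCC97H 680 genes were called, 41 by 2-fold, against 0 and 0 (1 of 10 each), the seed shift was 0.0060 in size against 0.111 (10 of 10), and 17 lists passed against 13 (1 of 10). Over 100 regroupings of both lines, 2 gave a difference between lines as large as the count of 1694, a share under 0.05. That share rests on the 79 regroupings that kept the groups of neither line, which called 0 or 1 genes. Each regrouped line also called 0 genes on its own, so the share does not exclude chance. Of the 21 regroupings that kept the groups of at least 1 line, the real one included, 2 were as large. The other one kept the Huh7 groups, exchanged MHCC97H miR-628-3p library 3 with vector library 2 and called 3221 genes, more than the real groups. It sorts the MHCC97H libraries by their trend with GC content. Deviations from the gene mean correlated with GC content at a Spearman rho of 0.229, 0.647 and 0.218 in miR-628-3p libraries 1 and 2 and vector library 2. In miR-628-3p library 3 and vector libraries 1 and 3 rho was -0.527, -0.369 and -0.232. The count of 1694 was not corrected for this trend, and after the GC and length correction it was 2007. For the 30 genes called alike in both lines 1 of 100 was as large, the real one, with a highest other of 0. Regrouping a line left 0 calls in it, which fixed the shared count at 0, so this says nothing on chance. For the correlation, with a size of 0.108, 72 of 100 were as large, up to 0.706, and chance is not excluded.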

How the results depend on the processing

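Voom and the GC and length correction were chosen after seeing the data. Robust eBayes, median rescaling, pooled UTRs and the other site definitions left the total counts of called genes and of lists within 1.5 times and each shift on the same side of 0, although the Huh7 genes called lower went from 1798 to 1121 after median rescaling. Genes with a 2-fold change numbered 30 in Huh7 and 81 in MHCC97H at pseudocount 0.1, 62 in MHCC97H at pseudocount 0.5, 25 in MHCC97H at a mean FPKM of at least 5, and 40 and 81 with voom. Without the expression filter 7 genes were called in Huh7 (0 by 2-fold), 326 in MHCC97H, 967 for the difference and 0 alike in both lines, and more genes were then tested. Quantile normalization left 2 lists in Huh7. Without the eBayes trend 1694 genes were called in Huh7 and 19 alike in both. One fit over all 12 libraries called 561 in Huh7 and 1584 in MHCC97H, with a shared spread. With the replicate number as a block, although the labels do not say that equal numbers pair the libraries, 1187 were called in Huh7, 1106 for the difference and 14 alike in both. Among protein-coding genes only, 56 were called alike in both. The GC and length correction left 1 gene in Huh7 (1 by 2-fold), a Huh7 seed shift of -0.017 (reversed), 1981 genes in MHCC97H and 0 alike in both. With an estimated correlation 0 lists passed in either line, and after the GC and length correction 1 did, ATF4 in MHCC97H (adjusted p = 0.0241). The alternative written for a table of counts (size factors with a Wald test, and no low-count filter) was planned only for deposited counts and was not run. Except where stated, the cause was not tested.

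Leaving out 1 library gave 0 to 1661 genes in Huh7 (0 to 24 by 2-fold) and 3 to 7 lists, with a seed shift of 0.0999 to 0.144. In MHCC97H it gave 142 to 1604 genes (36 to 48 by 2-fold), 15 to 21 lists and a seed shift of -0.072 to 0.054. For the lines together it gave 637 to 4670 genes with a difference, 0 to 56 alike and an r of -0.413 to 0.187.

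Log2 fold changes of single genes reversed as follows, none called in either direction under that setting. SOCS3 in MHCC97H was 0.0054 after median rescaling and 0.010 after quantile normalization, and ALB in Huh7 -0.027 after the latter. The GC and length correction gave 0.049 for CRB3, -0.022 for LIN28B, 0.0057 for ACADS, -0.0045 for ERO1A, 0.0073 for DUSP5 and -0.096 for CCL20 in Huh7, and 0.075 for RGS5 in MHCC97H. Without 1 library CDH1 in Huh7 ran from -0.113 to 0.012, SOCS3 in MHCC97H from -0.116 to 0.062 and RGS5 in MHCC97H from -0.172 to 0.035. Of 153 named values in Huh7 the GC and length correction left 8 with the same call, against 110 of 126 in MHCC97H, and voom left 146 and 119. A value uncalled both times counts as the same. Without the expression filter 9 of 153 and 85 of 126 were the same, and in the joint fit 52 of 152 and 112 of 125. Over the fits without 1 library 228 of 918 values in Huh7 and 499 of 751 in MHCC97H were the same. Depth limits genes near an FPKM of 1, which enter and leave with the filter.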

Other observations

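Other MHCC97H groups held called genes without passing as lists. Among proteases of invasion, MMP7 fell from 629 ± 7.93 to 387 ± 32.3 FPKM and the lysosomal protease CTSL from 716 ± 13.9 to 538 ± 19.7, beside PLAT, while the membrane protease MMP14 rose (camera adjusted p = 0.263 over 20 genes). Among TGF-beta targets the kinase inhibitor CDKN2B fell from 13.4 ± 0.0640 to 8.16 ± 0.633 FPKM and the matrix protein CCN2 fell to 9.39 ± 0.996 (log2 fold change -0.72), while TGFBI rose from 23.8 ± 1.19 to 30.6 ± 1.62 and SMAD7 from 3.54 ± 0.126 to 4.92 ± 0.344 (adjusted p = 0.263 over 20 genes). Among secreted angiogenic factors the EGFR ligand AREG fell from 13.9 ± 0.483 to 7.28 ± 0.853 FPKM and the ephrin EFNA1 rose from 19.7 ± 0.441 to 35.1 ± 7.69 (adjusted p = 0.103 over 13 genes). In fatty acid synthesis ACSL1 fell from 26.9 ± 0.186 to 17.6 ± 0.860 FPKM and ACSS2 from 27.5 ± 0.861 to 16.2 ± 1.60, while the lipid droplet protein PLIN2 rose from 74.7 ± 2.18 to 99.8 ± 5.01 (adjusted p = 0.283 over 22 genes). Among chaperones of the heat shock response CRYAB fell from 7.83 ± 0.527 to 4.06 ± 0.595 FPKM and HSPA8 from 872 ± 25.1 to 696 ± 31.6 (adjusted p = 0.103 over 17 genes).

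The control libraries of the lines, with a control mimic in Huh7 and the vector in MHCC97H, stood far apart in values given here without a test. Albumin ALB was at 6616 ± 246 FPKM in the Huh7 control and 13.9 ± 0.571 in the MHCC97H vector, the fibrinogen chain FGB at 688 ± 29.7 and 3.86 ± 0.278, and GJA1 at 259 ± 5.57 and 0.610 ± 0.0570. HMOX1 was at 20.3 ± 0.943 FPKM in Huh7 and 271 ± 19.6 in MHCC97H, and the adhesion gene CDH17 at 5.29 ± 0.164 and 79.1 ± 0.601. Mitosis genes had a positive median in both lines before and after the GC and length correction, at 0.15 and 0.12 in Huh7 and 0.09 and 0.14 in MHCC97H.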
